A study of Mus musculus with 8 samples.

How the data were processed

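RNA was sequenced from AtT-20 cells, a mouse pituitary corticotrope cell line, carrying an introduced ER-Pax7, a form of the transcription factor Pax7 that is activated by tamoxifen. The 8 libraries fall into 4 groups of 2, taken after 0, 24, 48 and 72 h of tamoxifen, and each library was assigned to its group and replicate number by its label. Per the labels' protocols, RNA was extracted with a column kit and ribosomal RNA was depleted. The labels' molecule field names genomic DNA, but the extraction protocol and the series design name RNA, and 17726 of 55401 genes were at 0 in every library; the values were read as RNA. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. No batch is labelled. Libraries of cells given vehicle for matched times were not used here. The cells of all 8 libraries carry ER-Pax7. Effects of its activation, of tamoxifen itself and of hours in culture therefore cannot be told apart.

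The deposited values were read as a signal, the mean read coverage over the merged exons of each gene, normalized by the authors. The unit was worked out from the values and the columns; the rule of scaling is not given in the sources used here. HISAT2 2.2, SAMtools 1.12 and deepTools 3.5 and the builds mm10 and GRCm38 are named, per the submitters' processing notes. The counting tool, its use of strand and the annotation release are not given in the sources used here, so antisense and overlapping genes cannot be separated. Of the gene identifiers, 55141 (99.5%) occur in GENCODE M21 and 54821 genes have the same coordinates there; all coordinates are GRCm38. Each gene had 1 value per library, so transcript isoforms were not tested.

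Summed signal was 164236 to 178548 per library. Read depth is not given. Low values came in steps of 0.0122 to 0.0170; what 1 step stands for is not given, so no read counts or counting intervals are given. Reads over bases that belong to several genes count for each of them, and 2077 tested genes (21.6%) have over 10% of their exonic bases inside exons of another gene. In 12 runs of at least 3 neighbours, 62 genes in all, values were equal within 5% across the libraries. In 6 of these runs, with 39 genes, protocadherin genes for the most part, every member has over 10% of its exonic bases inside exons of another gene; the other runs were not tested for a cause.

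Genes with a mean signal of at least 1 over the 8 libraries were tested (9606 genes). Values were transformed as log2(signal + 1), so fold changes on that scale understate the change of low genes; ratios of means are given beside them. A single limma 3.58.1 fit in R 4.3.3, with group as the only term and an intensity trend, had 4 residual degrees of freedom. Each contrast was adjusted by the Benjamini-Hochberg method over all tested genes at a threshold of 0.05, and adjusted p-values in the text come from this limma fit unless another is named. An F test over the 3 contrasts with 0 h gave genes changed at any time. The plan foresaw per-million units, per-kilobase units and counts but not coverage, and the filter and pseudocount planned for per-million units were kept.

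Several genes of interest lie below that filter. They are reported from the planned fit without a filter and from a fit chosen after seeing the data, called the lower floor, with a mean of at least 0.1 and a pseudocount of 0.1 (17871 genes). The limma fit was tested on simulated data for 72 h against 0 h with 9606 genes. Noise was drawn independently for each gene and library, so variation shared between genes was not simulated. Folds were set on the log2(signal + 1) scale, and for low genes they stand for larger folds of the signal itself. The fit recovered 25 of 50 genes changed 1.25-fold, 42 of 50 changed 1.5-fold, 48 of 50 changed 2-fold and 50 of 50 changed 3-fold. The fit made 5 false calls. It made 0 calls at 24 h, where nothing had been changed.

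The groups, tests, gene lists and naming rule were fixed before the data were examined. There were 29 gene lists: melanotrope, corticotrope, other pituitary lineage, pituitary progenitor, myogenic, neuronal, fibroblast, immune and endothelial markers; DNA methylation, DNA demethylation, imprinted, germline, enhancer coactivator and heterochromatin genes; secretory granule, S phase, G2 and mitosis, CDK inhibitor and p53, estrogen response, cholesterol, ER stress, interferon, Wnt/TGF beta/Notch and immediate early genes; and ribosomal protein, mitochondrially encoded, nuclear oxidative phosphorylation and poly(A)-lacking RNA genes. The 23 lists with at least 3 tested genes were tested by camera with a preset correlation of 0.01 at each time against 0 h, adjusted over 69 tests, and by camera with an estimated correlation. The latter setting also uses the 4 residual degrees of freedom, so its p can rise without a higher correlation.

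Genes were named by rule: Pax7, Pcsk2, Drd2, Pomc, Tbx19, Neurod1, Pcsk1, Dnmt1, Uhrf1, Tet1, Tet2 and Tet3 in each comparison with 0 h; the 12 highest and 12 lowest fold changes at 72 h and 6 of each at 24 and 48 h; and 4 of each for 48 h against 24 h and 72 h against 48 h. These came from called genes whose replicates did not overlap, with a mean of at least 5 in the higher group and a symbol that is not a predicted or clone name. Up to 4 members with the smallest p were named for a list; some members that this rule names are not reported here. Other genes were chosen after their values were seen: Esr1, Oacyl, Rgs4, Enpp2, Tfeb, Appl2, Pcp4, Il13ra1, Klf6, the genes of the chromosome 12 region, the ribosomal RNA genes, and those that only the closing section names. So were Prss16 and Pom121l2 on chromosome 13.

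Overlaps between times were set beside 50 simulations of unchanged groups sharing the 0 h libraries. Alternatives were a replicate block, other pseudocounts and filters, rescaling by a trimmed mean of M values (own implementation in place of the planned count package, since the values are not counts), quantile normalization, no trend with robust moderation, only the 4 libraries compared, protein coding genes, a minimum effect, fry, and leaving out each library. The lower floor and a set of 6334 genes without overlap and outside the 12 runs of near-equal neighbours were added after seeing the data. The chromosome 12 stretch described below is in none of these runs, so that rule did not remove its genes. Tests on raw counts or recovered reads did not apply. Values were read with Python 3.11.15, pandas 2.3.3, and numpy 2.4.6, with the R package data.table (version 1.17.8), and figures drawn with matplotlib 3.10.9.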

Results

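Gene expression was followed in mouse AtT-20 cells, a corticotrope line that makes the hormone precursor Pomc, over 0, 24, 48 and 72 h of tamoxifen, which activates the introduced ER-Pax7. Pax7 is the pioneer transcription factor that specifies pituitary melanotropes, and the series title concerns DNA demethylation by this factor. A change from 0 h may come from ER-Pax7, from tamoxifen itself or from hours in culture, which cannot be told apart here. Each time had n = 2 libraries, and all errors are SD over those libraries. Summed signal was between 164236 and 178548 per library, between 9516 and 9608 genes had a signal of at least 1, and the 10 highest genes held 49.5% to 52.8% of the sum. The 0 h libraries correlated at r = 0.994 across genes, which are not independent replicates. At later times 0 of the 6 libraries lay nearest the other library of their own group. For example, 24 h replicate 2 was nearest 48 h replicate 2 (r = 0.995, against 0.984 within its group), and the 24, 48 and 72 h libraries correlated within their groups at 0.984, 0.985 and 0.978.

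The Pax7 locus (ENSMUSG00000028736.13, chromosome 4, 139737062 to 139833528, GRCm38) had a signal of 13.1 ± 0.252 at 0 h, 13.3 ± 1.11 at 24 h, 14.3 ± 0.126 at 48 h and 13.8 ± 0.677 at 72 h. These values may hold reads of the introduced ER-Pax7, and limma gave adjusted p = 0.918, 0.646 and 0.687 against 0 h. Esr1, the estrogen receptor gene, had 16.2 ± 0.364 at 0 h and 18.0 ± 0.0811 at 72 h (limma adjusted p = 0.260). Esr1 too may hold reads of the introduced gene.

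Ribosomal RNA signal differed between libraries. The mitochondrial ribosomal RNA mt-Rnr1 was at 25.1 in 72 h replicate 2, against 1.14 to 5.97 in the other 7 libraries, and was higher in replicate 2 than in replicate 1 at each of the 4 times. The summed mitochondrial coding genes ranged from 1941 to 2269. On chromosome 12, between the 7SL RNA genes Rn7s1 and Rn7s2, the neighbours Lrr1, Pole2 and Klhdc1 had near-equal values in the 0 h libraries, at 70.4, 69.9 and 70.2 in replicate 1 and at 314 each in replicate 2. Pole2 was at 2.50 and 2.15 in the 72 h libraries. In 48 h replicate 1 Pole2 was at 0.728 and Klhdc1 at 0.974, while Klhdc2 and Nemf were at 505 and 503. None of the genes between Rn7s1 and Rn7s2 was called in any comparison with 0 h. Such differences were not confined to that stretch. Beyond Rn7s2, Gm18113 went from 0.160 in 0 h replicate 2 to 73.5 in 48 h replicate 2, and Arf6 from 9.70 to 83.1. On chromosome 13, the neighbours Prss16 and Pom121l2 were near-equal within each library, at 85.7 each in 72 h replicate 1 and 2.78 each in replicate 2.

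**Figure D1:**
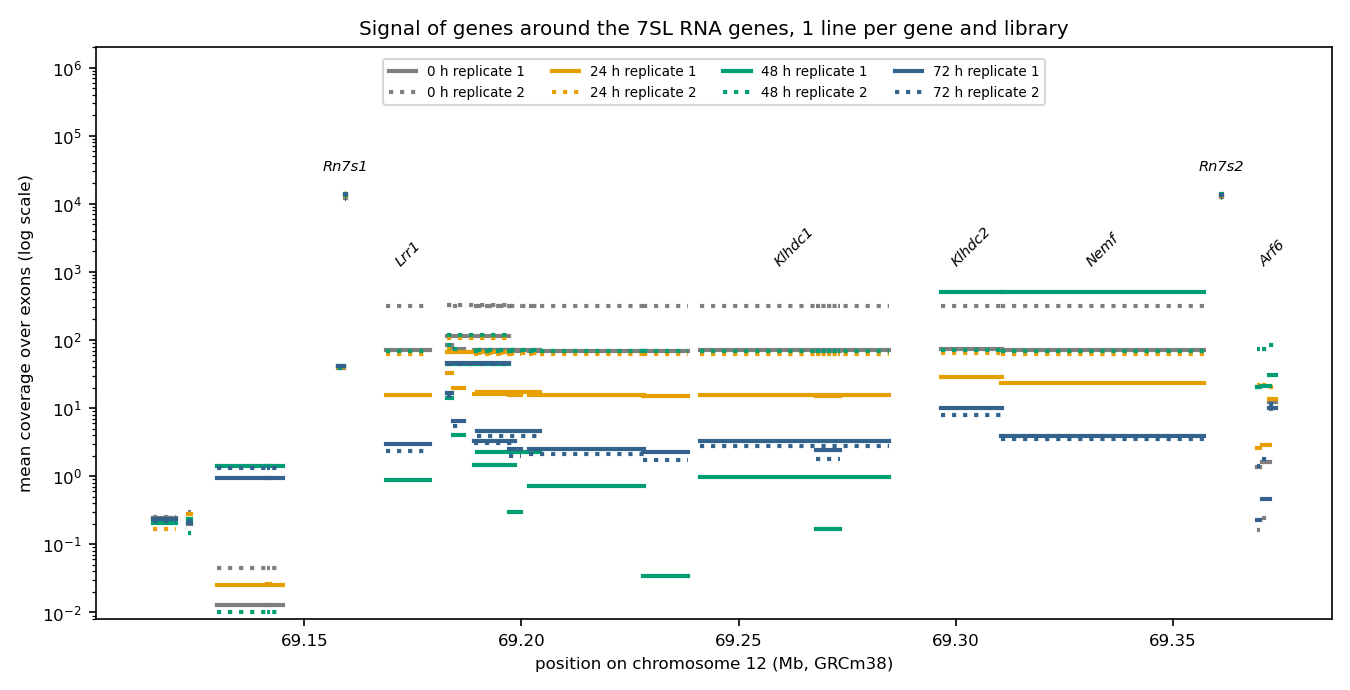
Signal (mean coverage over exons, log scale) of each gene by position on chromosome 12 (Mb, GRCm38), with 1 line per gene and library. In the 0 h libraries Lrr1, Pole2 and Klhdc1 lie at near-equal values, which differ between the replicates by a ratio of 4.48 for Pole2, while in 48 h replicate 1 Klhdc1 is at 0.974 and Nemf at 503.

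After 24 h of tamoxifen, Mest and Copg2 rose, and Tent5a, Ddc and the nuclear receptor gene Nr4a2 fell. Mest, an imprinted gene of the alpha/beta hydrolase fold family (ENSMUSG00000051855.15, chromosome 6, 30723547 to 30748465), rose 2.57-fold from 2.99 ± 0.0184 to 7.70 ± 0.445 (SE 0.05 on the log2 scale, limma adjusted p = 0.00103, n = 2 per group). Its convergent neighbour Copg2, a subunit of the COPI vesicle coat (chromosome 6, 30747554 to 30896794), rose 2.13-fold from 2.77 ± 0.0695 to 5.91 ± 0.213 (log2 0.87, limma adjusted p = 0.00114). These genes share 912 exonic bases, 23.1% of Mest and 17.8% of Copg2. Ank, a pyrophosphate transport protein gene, rose 1.60-fold from 3.80 ± 0.0915 to 6.08 ± 0.303 (log2 0.56, limma adjusted p = 0.0168).

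Tent5a fell at 24 h from 6.74 ± 0.229 to 3.24 ± 0.448 (log2 -0.87, limma adjusted p = 0.00838). Ddc, the decarboxylase that makes dopamine and serotonin (ENSMUSG00000020182.16, chromosome 11, 11814101 to 11898144), fell from 12.9 ± 0.610 to 7.27 ± 0.0207 (log2 -0.75, SE 0.06, limma adjusted p = 0.00838). Pex5l, Tbc1d1, Pglyrp1 and Mia3 also fell, with log2 changes of -0.54, -0.56, -0.49 and -0.35. In all, 22 of 9606 genes were called, 11 higher and 11 lower, and 1269 had an unadjusted p under 0.05. The count was 2 with either 0 h replicate left out, 8 without 24 h replicate 1, 104 without 24 h replicate 2, 12 with either 48 h replicate left out and 9 with either 72 h replicate left out. Of the 9 genes named by fold change, Mest and Copg2 kept their calls in each of the 8 such fits, and with either 0 h replicate left out these 2 alone kept them; the number kept was 4 without 24 h replicate 1, 6 with either 48 h replicate left out and 5 with either 72 h replicate left out.

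After 48 h, Mest stood at 9.30 ± 0.198 (3.11-fold, log2 1.37, limma adjusted p = 0.000255) and Copg2 at 6.79 ± 0.0549 (2.45-fold, log2 1.05, limma adjusted p = 0.000313). Mfge8, a secreted bridging protein for apoptotic cell uptake (ENSMUSG00000030605.15, chromosome 7, 79133768 to 79149060), rose 1.94-fold from 2.71 ± 0.0307 to 5.27 ± 0.244 (log2 0.75, SE 0.06, limma adjusted p = 0.00400). Rab27a, a GTPase of secretory vesicle docking, rose 1.78-fold from 4.26 ± 0.142 to 7.58 ± 0.381 (log2 0.71, SE 0.10, limma adjusted p = 0.0359). Ank and the epoxide hydrolase gene Ephx1 rose 1.65-fold and 1.54-fold.

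Among genes that fell by 48 h, Ddc reached 6.71 ± 0.568 (log2 -0.85, limma adjusted p = 0.00400). Igfbp5, which binds insulin-like growth factors, fell from 8.35 ± 0.392 to 4.86 ± 0.301 (log2 -0.67, SE 0.08, limma adjusted p = 0.0277). Tent5a, Pex5l, Pglyrp1 and the chromatin remodeller gene Chd9 fell by 0.69, 0.65, 0.62 and 0.51 on the log2 scale. There were 53 calls, 31 higher and 22 lower, and 1010 genes with an unadjusted p under 0.05. Quantile normalization gave 22 higher and 24 lower, and the replicate number as a block gave 14 higher and 10 lower, 24 in all. The count was 2 with either 0 h replicate left out, 95 with either 24 h replicate left out, 8 without 48 h replicate 1 and 7 without 48 h replicate 2. Mest and Copg2 alone of the 12 named by fold change kept their calls with either 0 h replicate left out; the number kept was 4 without 48 h replicate 1, 5 without 48 h replicate 2, 9 without 72 h replicate 1 and 10 without 72 h replicate 2.

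After 72 h, Mest reached 10.6 ± 0.260 (3.53-fold, log2 1.53, SE 0.05, limma adjusted p = 0.000112), Copg2 7.45 ± 0.00405 (2.69-fold, log2 1.17, limma adjusted p = 0.000147) and Mfge8 6.90 ± 0.285 (2.54-fold, log2 1.09, limma adjusted p = 0.000358). The neighbouring genes Ahsg and Fetub on chromosome 16, which code for the secreted proteins fetuin A and fetuin B, both rose. Ahsg (22891277 to 22899449) went 2.07-fold from 14.1 ± 0.210 to 29.3 ± 1.18 (SE 0.11 on the log2 scale, limma adjusted p = 0.00842), and Fetub (22918334 to 22939778) 1.67-fold from 7.15 ± 0.179 to 11.95 ± 0.572 (log2 0.67, limma adjusted p = 0.00390). Odc1, which begins polyamine synthesis, rose 1.79-fold from 7.47 ± 0.157 to 13.4 ± 1.53 (log2 0.76, SE 0.13, limma adjusted p = 0.0361). Rab27a, Ank, Tmem176a, Lbh, Ephx1 and Olfm1 rose by ratios of 1.79, 1.77, 1.73, 1.67, 1.66 and 1.65.

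Ddc fell at 72 h to 4.80 ± 0.0693, with log2 -1.26 (SE 0.06, limma adjusted p = 0.000358). Igfbp5 fell to 4.32 ± 0.158 (log2 -0.81, limma adjusted p = 0.00703), Pex5l to 3.82 ± 0.0987 (log2 -0.80, limma adjusted p = 0.000445) and Tent5a to 3.82 ± 0.00840 (log2 -0.68, limma adjusted p = 0.00952). App, the amyloid precursor protein gene, fell from 45.8 ± 0.627 to 33.0 ± 0.102, Chgb, a granule protein, from 87.5 ± 0.260 to 66.5 ± 2.48, and the microtubule regulator Stmn1 from 44.0 ± 0.617 to 33.6 ± 0.425. Chd9, Pglyrp1, Dner, Mir6916 and Mir1892 fell by 0.54, 0.43, 0.41, 0.40 and 0.47 on the log2 scale, and reads of host transcripts are not separated from those of either microRNA gene: Mir1892 lies wholly inside exons of Sptssa, and Mir6916 wholly inside the span of another gene, outside its exons. Below a mean of 5, and chosen after seeing the values, Rgs4, a regulator of G protein signalling, rose from 0.886 at 0 h to 1.497 at 24 h, 2.44 at 48 h and 3.51 at 72 h (log2 1.26, limma adjusted p = 0.000320 at 72 h). In the same way Enpp2 rose from 0.876 to 2.38, and the lysosomal regulator Tfeb from 0.456 to 1.41, while Appl2 fell from 3.66 to 1.67, Pcp4 from 3.45 to 1.51 and Il13ra1 from 3.96 to 2.16.

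At 72 h, 193 genes were called, 122 higher and 71 lower, of which 6 changed at least 2-fold on the log2(signal + 1) scale; 1505 had an unadjusted p under 0.05. The count was 16 without 0 h replicate 1, 9 without 0 h replicate 2, 313 without 24 h replicate 1, 320 without 24 h replicate 2, 79 without 48 h replicate 1, 78 without 48 h replicate 2, 23 without 72 h replicate 1 and 45 without 72 h replicate 2. Mest, Copg2, Mfge8, Ddc and Pex5l kept their calls in each of these 8 fits. Of the exonic bases of Mest, Copg2, Ddc and Pex5l, 23.1%, 17.8%, 26.9% and 49.1% lie inside the span of another gene. For Ank and Ahsg this share is 88.3% and 32.3%, and for Mfge8 it is 0. Reads of such neighbours are not separated. Of the 24 genes named by fold change, 6 kept the call without 0 h replicate 1, 5 without 0 h replicate 2, 8 without 72 h replicate 1, 11 without 72 h replicate 2 and 16 with either 48 h replicate left out.

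**Figure D2:**
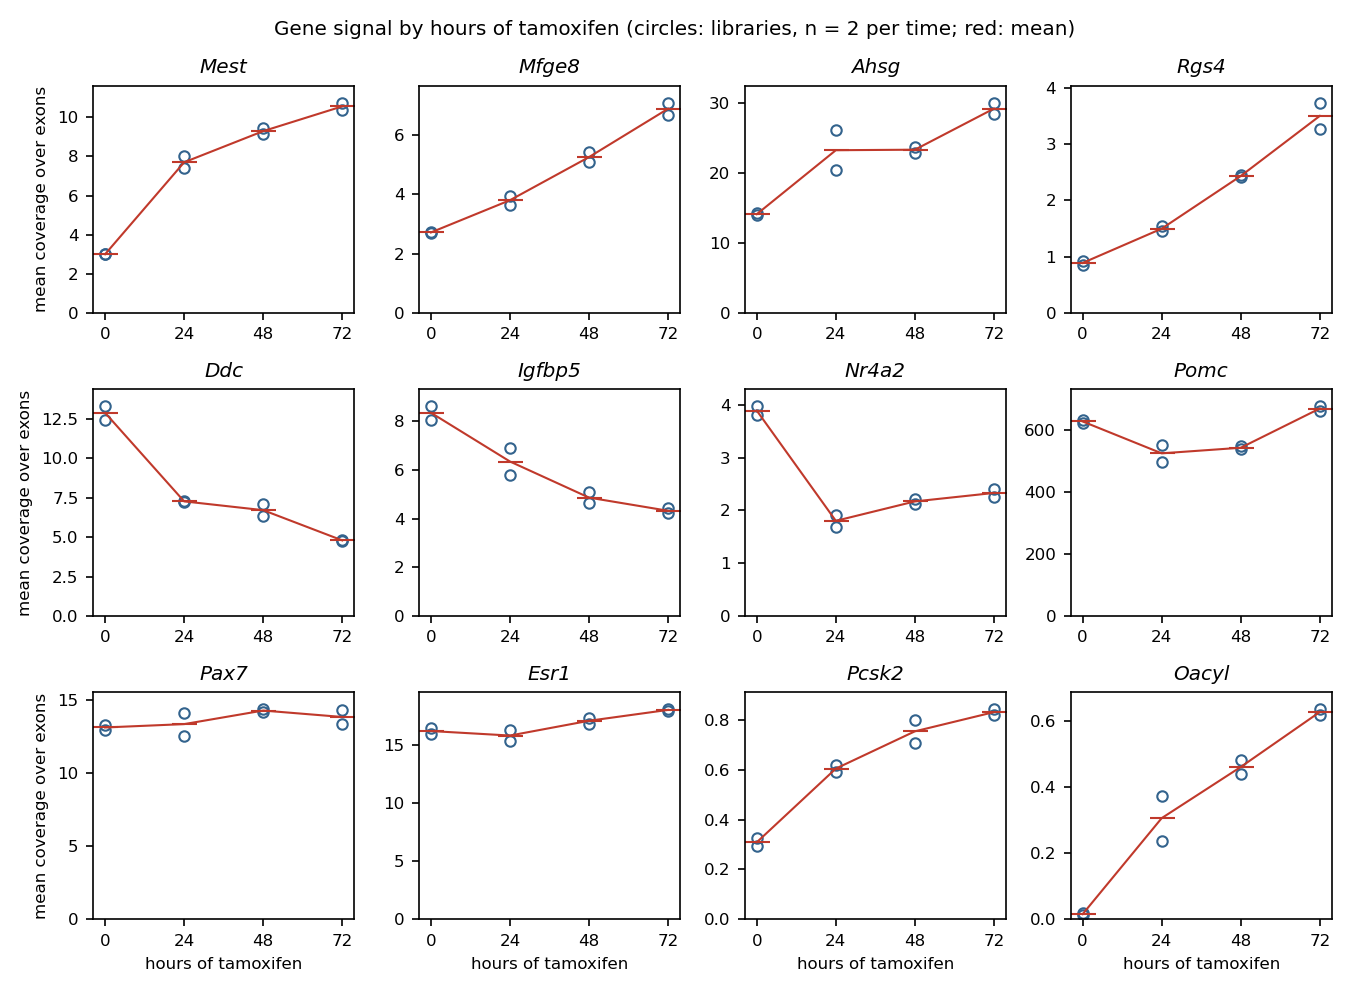
Signal (mean coverage over exons) of 12 genes against hours of tamoxifen, with each library as a circle (n = 2 per time) and the mean as a red line. Mest, Mfge8, Ahsg and Rgs4 are higher at 72 h than at 0 h, Ddc, Igfbp5 and Nr4a2 lower, and Pax7 stays between 12.6 and 14.4.

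Markers of the 2 pituitary cell types that share Pomc were compared next. Pomc had 629 ± 7.67 at 0 h, 526 ± 37.7 at 24 h, 544 ± 6.41 at 48 h and 670 ± 11.5 at 72 h (limma adjusted p = 0.247, 0.377 and 0.626). Tbx19, the corticotrope and melanotrope factor needed for Pomc, had 18.2 ± 0.656 at 0 h, 17.9 at 24 h, 20.2 at 48 h and 22.8 ± 0.520 at 72 h (limma adjusted p = 0.898, 0.632 and 0.122). Neurod1 had 4.27 and 5.03 (adjusted p = 0.185 in limma), and the prohormone convertase Pcsk1 had 18.7, 15.6, 18.7 and 22.9 over the 4 times (limma adjusted p = 0.278 at 24 h and 0.151 at 72 h). Among the 10 tested genes of the corticotrope list, the nuclear receptor Nr4a2 fell from 3.89 ± 0.124 to 1.80 ± 0.158 at 24 h (log2 -0.80, limma adjusted p = 0.00436) and stood at 2.33 ± 0.101 at 72 h (adjusted p = 0.00685 in limma). Nr3c1, the glucocorticoid receptor gene, stood at 3.56 ± 0.180 at 72 h, with a fall of log2 -0.40 (adjusted p = 0.0440 in limma).

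The melanotrope convertase Pcsk2 (ENSMUSG00000027419.9, chromosome 2, 143546156 to 143816285) lay below the filter, at 0.309 ± 0.0224, 0.606 ± 0.0221, 0.756 ± 0.0651 and 0.833 ± 0.0165 over the 4 times. Without a filter, limma gave log2 0.29, 0.42 and 0.49 and adjusted p = 0.209, 0.0873 and 0.0402, so Pcsk2 was called higher at 72 h in that fit. With the lower floor, chosen after seeing the data, it gave log2 0.79, 1.06 and 1.19 and adjusted p = 0.0446, 0.0107 and 0.00425. Oacyl, another gene of the melanotrope list, stood at 0.0150, 0.306, 0.460 and 0.627 (limma without a filter at 72 h, log2 0.68 and adjusted p = 0.0402). Leaving out libraries was not run for Pcsk2 or Oacyl, so how far their calls rest on single libraries is not known. Drd2, the dopamine receptor of melanotropes, was listed at 0 in every library. The melanotrope list had 3 tested genes, Pax7, Megf11 and Pkib, with 0 called by limma and camera adjusted p = 0.811, 0.549 and 0.458; at 24 h its median was 0.02 and its mean -0.01, and camera gave a direction of lower.

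DNA demethylation is the process named in the series title, and no gene of the DNA methylation and demethylation lists was called by limma at any time. Dnmt1, the maintenance methyltransferase, had 11.5 at 0 h and 12.2 at 72 h (limma adjusted p = 0.606), and its partner Uhrf1 5.92 and 5.78 (limma adjusted p = 0.886). Tet3 had 1.47 and 1.59 (limma adjusted p = 0.608). Tet1 at 0.319 and 0.259, and Tet2 at 0.507 and 0.417, lay below the filter and gave adjusted p = 0.705 and 0.772 in limma without it. Of 12 tested DNA methylation genes, limma called 0, and camera gave adjusted p = 0.361, 0.556 and 0.647; of 17 DNA demethylation genes, limma called 0, and camera gave adjusted p = 0.437, 0.469 and 0.656. Adjusted over the list alone, Ogt of the DNA demethylation list fell at 72 h, from 2.16 to 1.62. The 21 heterochromatin genes gave camera adjusted p = 0.469, 0.825 and 0.469, and at 24 h their median was 0.01 against a mean of -0.02 and a camera direction of lower.

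Of the secretory granule genes, 19 of 22 tested members were lower at 24 h, with a median log2 change of -0.15. Camera gave adjusted p = 5.729e-07 at 24 h and 0.00522 at 48 h, with adjusted p = 0.511 and 0.799 with an estimated correlation; at 48 h fry gave adjusted p = 0.140. At 24 h limma called 0 of them over all genes, and 1 higher and 9 lower adjusted over the list alone. The granule proteins Chgb and Chga had 87.5 ± 0.260 and 137 ± 0.564 at 0 h and 63.8 ± 2.84 and 105 at 24 h, Snap25, a fusion protein, 12.7 ± 0.0175 and 9.87 ± 0.647, and Nucb2 1.82 and 1.34. At 48 h 14 of 22 members were lower, with a median of -0.12, Rab27a was called higher, and adjusted over the list alone 2 were higher and 9 lower. At 72 h camera gave adjusted p = 0.285, with a median of 0.00, a mean of -0.03 and a direction of lower; Rab27a and Pam rose, Sytl4, Chgb and Snap25 fell, and adjusted over the list alone 2 were higher and 8 lower. Pam, which amidates peptide hormones, went from 7.45 ± 0.400 to 10.3 ± 0.00348, and Sytl4 from 4.13 ± 0.108 to 2.82 ± 0.232.

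Cholesterol genes were lower at 24 h and higher at 72 h. At 24 h 15 of 20 members were lower (median -0.13, camera adjusted p = 0.00102, adjusted p = 0.799 with an estimated correlation); limma called 0, and 1 was lower adjusted over the list alone. Nsdhl had 1.32 at 0 h and 0.946 at 24 h, Hmgcs1 4.03 and 3.25, and Fdps 9.54 and 7.59. Without 24 h replicate 1 camera gave adjusted p = 0.272. At 72 h 16 of 20 were higher (median 0.07, camera adjusted p = 0.0474, adjusted p = 0.799 with an estimated correlation), with 0 called by limma and 0 adjusted over the list alone; Dhcr7 had 5.47 and 7.49, Stard4 3.89 and 5.15, and Srebf2 2.55 and 3.14. That call was lost with a pseudocount of 0.1 (camera adjusted p = 0.0504) and without 0 h replicate 1, 0 h replicate 2 or 72 h replicate 2 (camera adjusted p = 0.0658, 0.0965 and 0.227). With the replicate number as a block the 72 h call was lost too (camera adjusted p = 0.0525). Fry, which does not compare a list with other genes, gave adjusted p = 0.426 at 24 h and 0.466 at 72 h in place of camera. At 48 h camera gave adjusted p = 0.0502, and between 0.0248 and 0.0447 without 24 h replicate 1, 24 h replicate 2, 48 h replicate 2 or 72 h replicate 1; it gave 0.0476 with the trimmed mean rescaling and 0.0464 with quantile normalization.

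All 7 tested estrogen response genes were lower at 24 h (median -0.13, camera adjusted p = 0.00227, adjusted p = 0.511 with an estimated correlation). At 48 h 6 of 7 were lower (median -0.14, camera adjusted p = 0.0346, adjusted p = 0.511 with an estimated correlation). The 7 include Esr1, which may hold reads of the introduced gene. Its log2 change was -0.03 at 24 h and 0.07 at 48 h (limma adjusted p = 0.8205 and 0.7396). Cited2 had 2.98 at 0 h and 2.35 at 24 h, Igfbp4 3.64 and 2.29, Cxcl12 3.56 and 3.14, and Ctsd 29.7 and 27.1; limma called 0, and 2 were lower adjusted over the list alone at 24 h and 0 at 48 h. The 48 h call was lost without 0 h replicate 2 (camera adjusted p = 0.260) or 48 h replicate 2 (0.124). At 72 h camera gave adjusted p = 0.403, with 2 higher and 3 lower adjusted over the list alone. Enhancer coactivator genes were lower at 24 h in 14 of 17 members (median -0.08, camera adjusted p = 0.00522, adjusted p = 0.511 with an estimated correlation), among them Smarcd3, Med1, Smarca2 and Smarcd2, with 0 called by limma and 0 adjusted over the list alone. That call was lost without 0 h replicate 2 (camera adjusted p = 0.108) or 24 h replicate 1 (0.0669); at 48 and 72 h camera gave adjusted p = 0.298 and 0.654, and at 72 h the median was 0.01 against a mean of -0.01 and a camera direction of lower.

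The corticotrope list was lower at 24 h by camera (adjusted p = 0.0494, adjusted p = 0.799 with an estimated correlation), with a median of -0.02 and a mean of -0.15. Nr4a2 was called, and Nr4a2, Nr3c1, Pomc and Pcsk1 were lower adjusted over the list alone. Fry gave adjusted p = 0.140. The camera call was lost with a pseudocount of 0.1 (camera adjusted p = 0.0524) and with the replicate number as a block (camera adjusted p = 0.0701). It was also lost in camera without 0 h replicate 2, 24 h replicate 1, 48 h replicate 1, 48 h replicate 2 or 72 h replicate 2, with adjusted p = 0.0965, 0.506, 0.0678, 0.0663 and 0.0523. At 48 h its median was 0.06, its mean -0.04 and the camera direction lower (adjusted p = 0.904). At 72 h 8 of 10 members were higher (median 0.16, camera adjusted p = 0.293), and adjusted over the list alone 4 were higher, Il6st and Tbx19 among them, and 2 lower.

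The imprinted list was higher at 48 h by camera (adjusted p = 0.0474, adjusted p = 0.592 with an estimated correlation), with 7 of 9 above 0 h. Its mean of 0.18 against a median of 0.07 rested largely on Mest, at log2 1.37. The list was not tested without Mest. Mest alone was called over all genes; adjusted over the list alone Mest, Peg13 and Impact were higher, Peg13 going from 1.24 to 1.56 and Impact from 1.28 to 1.64, while Plagl1 had 7.74 and 6.30. The camera call was lost without 0 h replicate 2, 24 h replicate 1, 24 h replicate 2, 48 h replicate 1 or 72 h replicate 2, with adjusted p = 0.0965, 0.107, 0.0838, 0.114 and 0.0553. At 24 and 72 h camera gave adjusted p = 0.706 and 0.0693, fry 0.0451 and 0.0216, and camera with quantile normalization 0.0464 at 72 h. Of 20 myogenic genes only 3 passed the filter, among them the transcription regulators Eya1 and Tcf12. All 3 were lower at 48 h (median -0.16, camera adjusted p = 0.0138, adjusted p = 0.511 with an estimated correlation) and 72 h (median -0.21, camera adjusted p = 0.00665, adjusted p = 0.511 with an estimated correlation), and each was lower adjusted over the list alone at both times, though limma called 0 over all genes. At 72 h Eya1 had 1.11 against 1.48 and Tcf12 1.41 against 1.72; at 24 h camera gave adjusted p = 0.209 for this list.

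**Figure D3:**
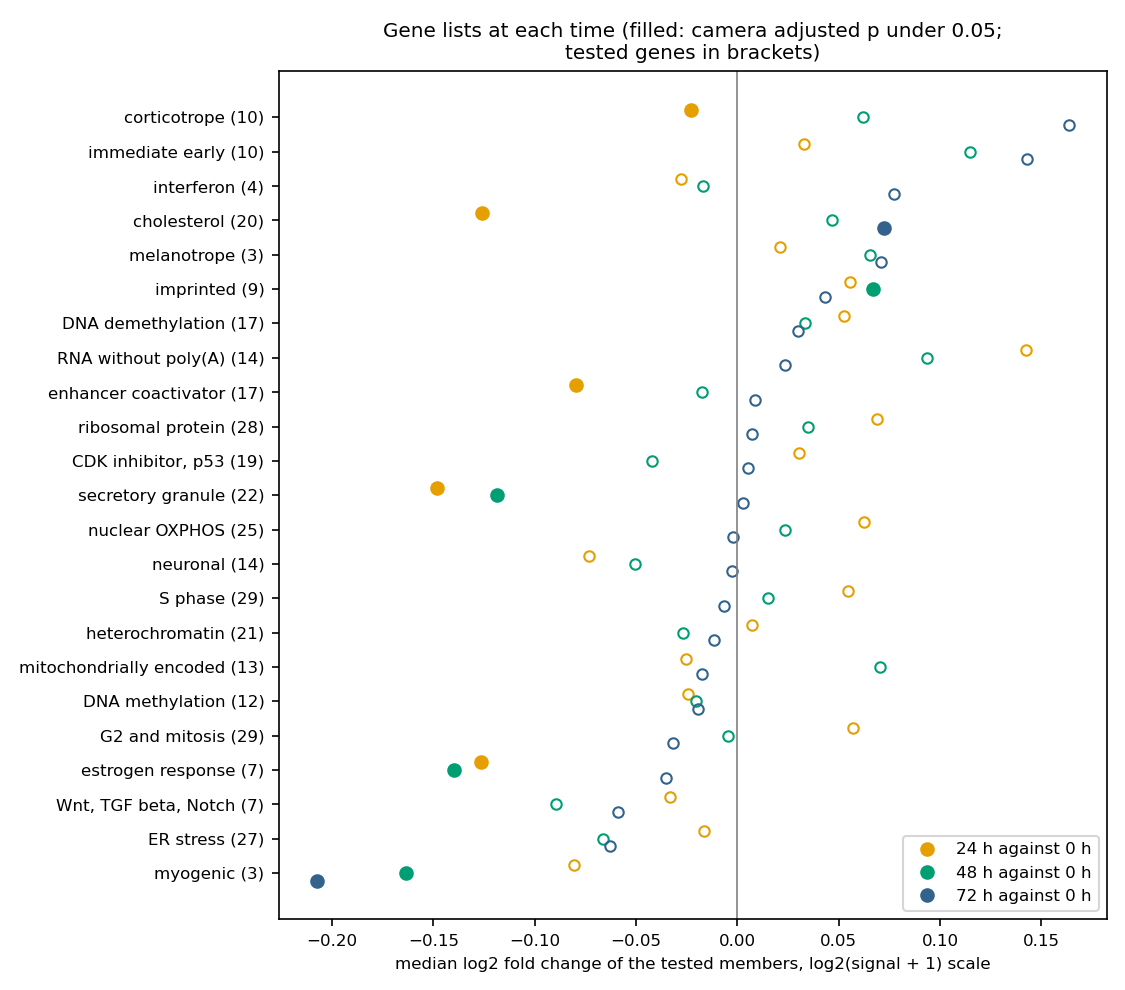
Median log2 fold change of the tested members of each list (log2(signal + 1) scale) at 24, 48 and 72 h against 0 h, with the number of tested members in brackets and filled circles for camera adjusted p under 0.05. With the preset correlation 5, 4 and 2 lists pass at 24, 48 and 72 h. With an estimated correlation, which also takes the 4 residual degrees of freedom, 0 pass.

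Other lists did not pass camera at any time with all 8 libraries and a mean signal of at least 1. With the lower floor, interferon and immediate early genes were higher and ER stress genes lower at 72 h (camera adjusted p = 0.00482, 0.00641 and 0.0498, and 0.657, 0.657 and 0.817 with an estimated correlation). At 72 h the adjusted p was 0.706 for 29 S phase genes, 0.437 for 29 genes of G2 and mitosis, 0.929 for 19 CDK inhibitor and p53 target genes, 0.107 for 27 ER stress genes, 0.136 for 10 immediate early genes, 0.437 for 4 interferon genes, 0.458 for 7 Wnt, TGF beta and Notch targets and 0.985 for 14 neuronal genes. The genes limma called within them at 72 h included Perp, which was lower, and Psmb8 and Elavl3, which were higher; Psmb8, an immunoproteasome subunit, went from 1.51 to 2.10 and Elavl3, a neuronal RNA binding protein, from 1.74 to 2.44. Adjusted over the list alone, 4 immediate early genes were higher at 72 h, Atf3, Junb, Dusp4 and Dusp5, and 1, Klf6, was lower, at 3.68 against 4.13. In the same way 1 neuronal gene was higher and 1 lower, 2 CDK inhibitor and p53 target genes higher and 1 lower, 1 interferon gene higher, and 1 Wnt, TGF beta and Notch target higher and 3 lower. For ribosomal protein, mitochondrially encoded, nuclear oxidative phosphorylation and poly(A)-lacking genes camera gave adjusted p = 0.956, 0.514, 0.956 and 0.727 at 72 h. Leaving out 1 library let some of these lists pass. Camera gave the mitochondrially encoded genes as lower without 0 h replicate 1 at 24 and 72 h (adjusted p = 0.00732 and 0.0241) and without 24 h replicate 2 at 24 h (0.0212), but as higher without 0 h replicate 2 at 48 h (0.00607). Without 24 h replicate 2 it gave G2 and mitosis, ribosomal protein and oxidative phosphorylation genes as higher at 24 h (camera adjusted p = 0.0411, 0.0132 and 0.00274). Immediate early genes were higher by camera at 24 h without 24 h replicate 1 (adjusted p = 0.0273) and at 48 h without 48 h replicate 1 (0.0468), and ER stress genes lower at 72 h without 72 h replicate 1 (0.0447). The oxidative phosphorylation genes had a median just below 0, a mean just above 0 and a camera direction of lower at 72 h. At 48 h the G2 and mitosis genes had a median just below 0 and a mean of 0.01, with a camera direction of higher. Markers of other cell types had too few genes to test at that filter: at most 2 genes of the other pituitary, progenitor, germline, fibroblast, immune and endothelial lists had a mean of at least 1. Their highest members were Gata2 at 1.49, Cd9 at 32.9, Rhox2a at 7.55, Twist1 at 1.73, Csf1r at 0.507 and Egfl7 at 1.18. With the lower floor 8 progenitor, 4 germline and 3 immune genes were tested, and none of these lists passed camera at any time. At 72 h camera gave adjusted p = 0.1216, 0.9075 and 0.5906, and 6 of the 8 progenitor genes were lower (median -0.20).

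The times were then compared with each other. Rgs4 and Mfge8 were higher at 72 h than at 24 h, by log2 0.85 (SE 0.06, limma adjusted p = 0.0150) and 0.72 (SE 0.06, limma adjusted p = 0.0167), and were the 2 genes called among 1302 with an unadjusted p under 0.05. That count was 0 without any 1 of the 0 h and 48 h replicates, 1 without 24 h replicate 1, 61 without 24 h replicate 2, 2 without 72 h replicate 1 and 1 without 72 h replicate 2. Of Rgs4 and Mfge8, 0 were among the calls without 24 h replicate 1, 2 without 24 h replicate 2 and 1 with either 72 h replicate left out. Between 24 and 48 h and between 48 and 72 h limma called 0 genes, with 762 and 576 at an unadjusted p under 0.05. The F test over all times called 33 genes. Its count was 3 with either 0 h replicate left out, 67 without 24 h replicate 1, 167 without 24 h replicate 2, 15 without 48 h replicate 1, 14 without 48 h replicate 2, 13 without 72 h replicate 1 and 8 without 72 h replicate 2.

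Of the 193 genes called at 72 h, 20 were also called at 24 h and 53 at 48 h, and 0 changed direction between called times. Mia3 and Tbc1d1 were called at 24 h and not at 72 h. All 11 genes higher at 24 h were among the 31 higher at 48 h, against 0.0355 for independent lists and a mean of 0.02 in simulations of unchanged groups. The simulated groups had at most 1 call per time and direction, so that their overlaps were bound to lie near 0. The 11 genes were also all among the 122 higher at 72 h, against 0.140 for independent lists and 0 simulated. For genes lower at 24 h, 8 of 11 were shared with 48 h and 9 with 72 h, against 0.0252 and 0.0813 for independent lists and 0 in the simulations. All 31 higher and 22 lower genes of 48 h were called at 72 h, against 0.394 and 0.163 for independent lists and 0 simulated. The fold changes of all genes correlated at 0.837 between 24 and 48 h, 0.731 between 24 and 72 h and 0.816 between 48 and 72 h, against 0.497, 0.500 and 0.506 simulated. Their covariances of 0.0363, 0.0357 and 0.0462 exceeded the simulated 0.0117, 0.0117 and 0.0118 by 0.0247, 0.0240 and 0.0344. The 2 control libraries were not split, which would have left 1 for each comparison, so part of the overlap may come from the shared controls. Noise was drawn independently for each library, so variation shared by libraries of different times was not simulated.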

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

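The tests of the chromosome 12 stretch, of the bases shared by Mest and Copg2 and of ribosomal RNA were chosen only after the result was seen; the test of the COPI coat genes was written before its result.

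Rgs4 and Mfge8 stood out because their change from 0 h differed between times: 72 h exceeded 24 h by 0.85 on the log2 scale for Rgs4 (SE 0.06, limma adjusted p = 0.0150) and by 0.72 for Mfge8 (SE 0.06, limma adjusted p = 0.0167). Both 72 h libraries lay above both 24 h libraries for each gene, at 3.27 and 3.74 against 1.45 and 1.55 for Rgs4 and at 6.70 and 7.10 against 3.65 and 3.96 for Mfge8. The number of genes called there was 0 without any 1 of the 0 h and 48 h replicates, 1 without 24 h replicate 1, 61 without 24 h replicate 2, 2 without 72 h replicate 1 and 1 without 72 h replicate 2; of the 2 genes, these held 0, 2, 1 and 1 in the last 4 cases.

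Between Rn7s1 and Rn7s2 on chromosome 12, Lrr1, Pole2 and Klhdc1 had near-equal values within each 0 h library. Hours of tamoxifen alone are argued against by the 0 h libraries of Pole2, at 69.9 and 314, a ratio of 4.48. Coverage added alike over neighbouring genes is a candidate explanation: after subtracting Gm47545, a predicted gene at 0.0346 in 48 h replicate 1, most of the other 12 genes kept a level of their own over the libraries, such as 3.75 to 4.56 for Mgat2 and 0.528 to 1.02 for Klhdc1, and their median ratio of highest to lowest library was 1.77 (178 before), with 8 of 12 under 3. A single added level over the whole stretch is argued against, since the same subtraction left Klhdc2 and Nemf at 505 and 503 in 48 h replicate 1 and at 13.6 and 8.25 in 24 h replicate 1, so that the highest library of Klhdc2 was 172 times its lowest and that of Nemf 607 times. The source of added coverage was not tested, nor was a biological explanation beyond the hours of tamoxifen.

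Copg2 rose beside Mest, whose exons overlap its own by 912 bases. A shared rise of COPI coat genes is argued against: the other 7 tested subunits had a median log2 change of 0.03 at 72 h, with 5 above 0, and camera gave p = 0.271 (0.558 with an estimated correlation). Signal from Mest over the shared bases alone is not excluded, since the signal added over Copg2 was 80.2% of that added over Mest. Only more added signal than over Mest would have excluded it. It would need 26.3 of added coverage over those bases, while the mean over all exons of Mest went from 2.99 to 10.6. The added coverage would thus have to be higher over the shared bases than over the rest of Mest, which was not tested. With 1 value per gene and no statement on strand, signal from Mest over the shared bases and a rise of Copg2 itself cannot be told apart.

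Ribosomal RNA was high in 72 h replicate 2. Hours of tamoxifen alone are argued against, since mt-Rnr1 was at 1.23 in 72 h replicate 1, below both 0 h libraries, and at 25.1 in replicate 2. Less complete removal of ribosomal RNA in that library is a candidate explanation: mt-Rnr1, mt-Rnr2 and Gm23935, a short gene annotated as a microRNA whose signal followed theirs, were at least 3.40 times the highest other library, while the summed mitochondrial coding genes were 0.932 times those of replicate 1.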

How the results depend on the processing

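The lower floor and the set of genes without overlap were chosen only after the data were seen; the other alternatives were planned. Among genes named by rule at their times, 1187 values kept their direction and side of the threshold over all alternatives, 290 lost and 2 gained a call, and 0 reversed. These values come from 69 entries of a gene at a time. Of them, 9, 12 and 24 at 24, 48 and 72 h were called and named by fold change. The others, such as Pax7 and Pomc, had no call to lose, so all 290 losses fall on the called entries. Calls were lost most often with a tested minimum effect (45), with an absolute log2 change of at least 1 (37), without 0 h replicate 2 (36) or 1 (35) and without a filter (28). A lone library left in a group is assumed to vary like the other groups. Read depth is not given, so what depth limits was not measured. Transcript isoforms were not run, since there was 1 value per gene, and tests on raw counts or recovered reads did not apply. Unless stated, the cause was not tested.

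Without a filter on low values, limma called 4 genes at 24 h, 5 at 48 h, 63 at 72 h, 0 for 72 h against 24 h and 6 at any time. With a stricter filter of 5 it called 9, 22, 63, 0 and 11. With only the 4 libraries compared it called 1 at 24 h, 111 at 48 h and 0 for 72 h against 24 h. Among protein coding genes it called 45 at 24 h and 98 at any time, and without trend and with robust moderation 80 at any time. With the lower floor it called 98 at 48 h and 63 at any time, and 6 lists passed at 72 h. A tested minimum effect of 2-fold gave 0 at 24, 48 and 72 h and 0 for 72 h against 24 h, by its own construction a stricter test. Calls with an absolute log2 change of at least 1 numbered 1, 2, 6 and 0 in that order; between times they shared 1 higher and 0 lower for 24 and 48 h, 1 and 0 for 24 and 72 h, and 2 and 0 for 48 and 72 h.

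With the replicate number as a block, limma called 24 genes at 48 h and 1 for 72 h against 24 h, and 1 list passed at 72 h; camera gave adjusted p = 0.0525 for cholesterol genes at 72 h and 0.0701 for the corticotrope list at 24 h, and the block changed no other list's call and moved no other count by over 1.5 times. Deviations of equally numbered libraries correlated at 0.18, 0.34, -0.02, 0.40, 0.10 and 0.07 over the 6 pairs of groups, not all over 0.1, and the labels give no pairing, so the numbers were not taken to pair the libraries. As a hint from the data, 5 of the 6 later libraries lay nearest one of their own number, and mt-Rnr1, mt-Rnr2 and Gm23935 were higher in replicate 2 at all 4 times. Along the 3rd principal component replicate 1 lay above replicate 2 at all 4 times. A shared effect of the replicate number is therefore not excluded. With an estimated correlation 0 lists passed at 24, 48 and 72 h. The estimate was above the preset 0.01 for secretory granule, cholesterol, corticotrope and imprinted genes, at 0.16, 0.33, 0.31 and 0.02. For estrogen response, enhancer coactivator and myogenic genes it was below, at 0.008, -0.04 and -0.15. Their calls were therefore not lost to a higher correlation, and that setting also uses the 4 residual degrees of freedom. With a pseudocount of 0.1, where the cholesterol list was lost, 1 passed at 72 h. Leaving out 1 library at a time gave 2 to 104 genes at 24 h, 2 to 95 at 48 h, 9 to 320 at 72 h, 0 to 1 for 48 h against 24 h, 0 to 1 for 72 h against 48 h, 0 to 61 for 72 h against 24 h and 3 to 167 at any time, and 3 to 9, 3 to 5 and 1 to 3 lists at 24, 48 and 72 h. The lowest gene counts against 0 h came without a 0 h library and the highest without a 24 h library.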

Other observations

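The lower floor and the test of neighbouring genes were chosen only after the data were seen; the tests of NRF2 targets and lysosomal genes were written before their results. With the lower floor, which reaches weakly expressed genes, limma called 29 genes at 24 h, 98 at 48 h and 281 at 72 h among 17871. For the 5 tested genes of the melanotrope list camera gave a direction of higher, with adjusted p = 0.0394, 0.00141 and 0.00141 at 24, 48 and 72 h (adjusted p = 0.574, 0.328 and 0.328 with an estimated correlation). That rested on Pcsk2 and Oacyl, the 2 called, whose low levels were among the reasons for this floor: medians were 0.11, 0.12 and 0.18 against means of 0.51, 0.71 and 0.83, and 4, 4 and 5 genes were above 0. Oacyl went from 0.0150 at 0 h to 0.627 at 72 h (log2 2.66, SE 0.17, limma adjusted p = 0.00135). At 72 h 15 of 16 interferon genes were higher (camera adjusted p = 0.00482, adjusted p = 0.657 with an estimated correlation), as were 11 of 16 immediate early genes (camera adjusted p = 0.00641, adjusted p = 0.657 with an estimated correlation). ER stress genes were lower in 19 of 28 (camera adjusted p = 0.0498, adjusted p = 0.817 with an estimated correlation). Adjusted over the list alone, 3 interferon genes were higher, 8 immediate early genes higher and 1 lower, and 0 ER stress genes called.

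Other genes called at 72 h with the lower floor were low at 0 h. Sytl2, a Rab27 effector of vesicle docking, rose from 0.261 to 1.15 (log2 1.79, limma adjusted p = 0.00196), beside the rise of Rab27a. The receptor gene Kit rose from 0.206 to 0.521, Cilp from 0.0540 to 0.464, Gprc5b from 0.317 to 0.780 and Mybpc1 from 0.0536 to 0.351. The steroid-metabolising enzyme gene Akr1c14 fell from 1.62 to 0.447 (log2 -1.65, limma adjusted p = 0.000451). The long noncoding RNA Rmst fell from 0.550 to 0.162, Fxyd3 from 0.489 to 0.153, Astn2 from 0.508 to 0.0752 and the transcription factor gene Ebf3 to 0.472 (log2 -0.95). Leaving out libraries was not run with the lower floor for these genes.

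Tfeb, a regulator of lysosomal genes, rose at 72 h, and the hypothesis that other lysosomal genes rose was tested. Of 20 tested genes 7 were higher, with a median log2 change of -0.04, and camera gave p = 0.0512 (0.137 with an estimated correlation) in the direction of a fall. Ephx1, Gstp1 and G6pdx, often listed as targets of the stress regulator NRF2, rose by log2 0.62, 0.54 and 0.32, and the hypothesis that other NRF2 targets rose was tested likewise. Of 14 genes 8 were higher, with a median of 0.01, and camera gave p = 0.982 (0.982 with an estimated correlation). Neither test showed a rise, but both lists left out genes already seen among the calls, and a list built so cannot exclude a rise, although the bound written beforehand was met.

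The neighbours Ahsg and Fetub raised the hypothesis that called genes lie near each other. Setting aside shared bases and gene families, 140 called genes at 72 h held 4 pairs of the same direction within 100 kb: Irgm2 and Zfp672, 1700086L19Rik and Dbpht2, Olfm1 and Gm13373, and Parp16 and Clpx. Random picks from 6334 tested genes held a mean of 1.61 such pairs over 10000 picks, and a permutation test gave p = 0.0828, so clustering and chance cannot be told apart with 4 pairs.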
